A study of Mus musculus with 37 samples.

How the data were processed

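Gene expression was measured by RNA sequencing in liver and brain cortex of mice aged 10 months, 37 libraries in all. Per the labels, the genotypes were WT, TDP-43Q331K (a knock-in of the Q331K change in Tardbp, the gene of the RNA-binding protein TDP-43), TMEM106B-/- (loss of the lysosomal membrane protein TMEM106B) and the combined genotype TMEM106B-/- TDP-43Q331K. Per the labels, total RNA was taken up in Trizol and libraries were made with a directional kit. Per the submitters' processing notes, reads went through Trim Galore, cutadapt and FastQC, and the genome builds were GRCm38 and mm10. The aligner, the counting program, the strand setting and all versions of these steps are not given in the sources used here. The values are deposited counts, whole-number raw counts per gene with no normalization. Each table held 55536 genes, and all 55536 matched the GENCODE M21 annotation by identifier. The cortex table held 1 column with no sample in the labels, which was not used here.

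The liver libraries held 50.5 to 74.1 M counts and the cortex libraries 28.8 to 46.3 M counts. Precision was set by the spread between libraries more than by depth. The common biological coefficient of variation was 0.235 in liver and 0.103 in cortex. The labels do not say whether each library came from a separate animal, so the p-values measure only the spread between these samples.

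Groups were taken from the labels, 4 genotypes in each of 2 tissues. Each tissue was fitted alone, with its 4 genotypes in the same model, in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 16710 genes in liver and 21248 in cortex. Libraries were scaled by TMM and tested with the robust quasi-likelihood test, with 12 residual degrees of freedom in liver and 17 in cortex. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes under an adjusted p of 0.05 were called. The 6 comparisons per tissue were 5 pairwise contrasts and the interaction, the difference between the effect of TMEM106B loss with and without TDP-43Q331K. Errors on log2 fold changes are standard errors (SE), and those on counts scaled to library size and given per 1 M (CPM) and scores are standard deviations (SD).

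Before the data were examined, 47 gene lists with 898 gene names were written for pathways, organelles, cell types and neighbouring tissue. The annotation lacked 2 of these names. Lists with at least 4 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), 30 lists in liver and 33 in cortex. Camera asks whether a list moved relative to the other genes. It was also run with an estimated correlation between genes, which is the stricter test, and fry asked whether the members moved on balance in the same direction without comparing them with other genes. Counts of called members are given over all genes and adjusted over the list alone. A list score is the mean log2 CPM of its members in a library minus the WT mean.

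The comparisons, the lists, the alternatives and the rule for naming genes were also chosen at that time. The rule named Tmem106b and Tardbp, the 12 called genes per direction with the smallest p, 4 members per passing list, 6 interaction genes per direction, up to 10 genes shared between comparisons or tissues, and chromosomal neighbours of the targeted genes. The text gives a part of these. The pipeline was tested on simulated data in which 200 genes were changed, 100 by 1.5-fold and 100 by 3-fold. In liver 14 to 22% of the 1.5-fold and 70 to 78% of the 3-fold changes were recovered, and in cortex 53 to 68% and 94 to 97%. No simulated gene was called in the wrong direction, and 2 to 7.19% of calls were false.

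The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE size factors, no filter on low counts, a fit of only the compared groups, replicate number as a block, 1 surrogate variable (sva 3.50.0), and each library left out in turn. Other splits of the libraries into groups of the same sizes were also counted. A sex covariate was not run, since all libraries carried the Y-linked transcript Ddx3y (lowest 40.2 CPM) and Xist reached at most 0.385 CPM. A pair of alternatives was chosen after seeing the data. The first leaves out 3 livers with high acute phase transcripts (WT replicate 2, TMEM106B-/- replicate 4 and the combined genotype's replicate 1) and 4 cortices with extreme tissue markers (WT replicate 1, TDP-43Q331K replicate 3, TMEM106B-/- replicate 5 and the combined genotype's replicate 2). The second adds scores of deep layer, striatum and meninges markers as covariates in cortex.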

Results

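RNA was sequenced from liver and brain cortex of mice aged 10 months. In liver each of the 4 genotypes had 4 libraries. In cortex there were 5 WT, 6 TDP-43Q331K, 5 TMEM106B-/- and 5 TMEM106B-/- TDP-43Q331K libraries, and the last of these is called the combined genotype here. The series asks which expression changes follow TMEM106B deficiency and TDP-43 Q331K in brain and liver, with lipid metabolism and obesity in its title. Values after gene names are log2 fold changes ± SE from edgeR unless a fold is named, and list tests are from camera. The median log2 fold change of all genes lay between -0.029 and 0.00894 in every comparison.

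The RNA of the targeted gene did not fall with the label. Tmem106b (ENSMUSG00000029571, GRCm38 chromosome 6, 13069759 to 13089269, plus strand) was at 96.5 ± 16.3 CPM (SD, n = 4) in WT liver, 91.9 ± 21.3 in TDP-43Q331K, 115.3 ± 9.32 in TMEM106B-/- and 135.1 ± 9.15 in the combined genotype. No edgeR comparison of libraries labelled TMEM106B-/- with their controls called it lower. It was 1.47-fold higher in liver of the combined genotype than in TDP-43Q331K (0.56 ± 0.15, adjusted p = 0.0497, 4 of 4 libraries). That call was lost when only the compared groups were fitted, with 1 surrogate variable, without the high acute phase livers (chosen after seeing the data), and without any single library of the 8 other than TDP-43Q331K replicate 1. The adjusted p was between 0.0133 and 0.126 over the alternatives. In cortex the gene was at 188.0 ± 4.69 CPM (SD, n = 5) in WT, 181.3 ± 6.79 (n = 6) in TDP-43Q331K, 184.2 ± 6.66 (n = 5) in TMEM106B-/- and 200 ± 13.5 (n = 5) in the combined genotype. RNA counts cannot tell a loss that leaves the RNA from wrong labels, so genotypes and directions for TMEM106B loss below rest on the labels. Tardbp (ENSMUSG00000041459, chromosome 4, 148612382 to 148627019, minus strand) was not called by edgeR in any comparison. In cortex it stood at 157.2 ± 5.44 CPM (n = 5) in WT and 177.9 ± 5.78 (n = 6) in TDP-43Q331K (0.18 ± 0.04, edgeR adjusted p = 0.431), and it passed there with limma-voom alone (adjusted p between 0.0461 and 0.961 over the alternatives). Between the combined genotype and TDP-43Q331K in cortex (-0.17 ± 0.04, edgeR adjusted p = 0.0513) it passed with RLE size factors, 1 surrogate variable, limma-voom, DESeq2, the marker scores, without the cortices with extreme markers and without replicate 5 of the combined genotype (adjusted p between 0.00871 and 0.117 over the alternatives). In liver it was between 106.0 ± 7.74 and 115.6 ± 18.8 CPM (n = 4) in the group means.

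**Figure D1:**
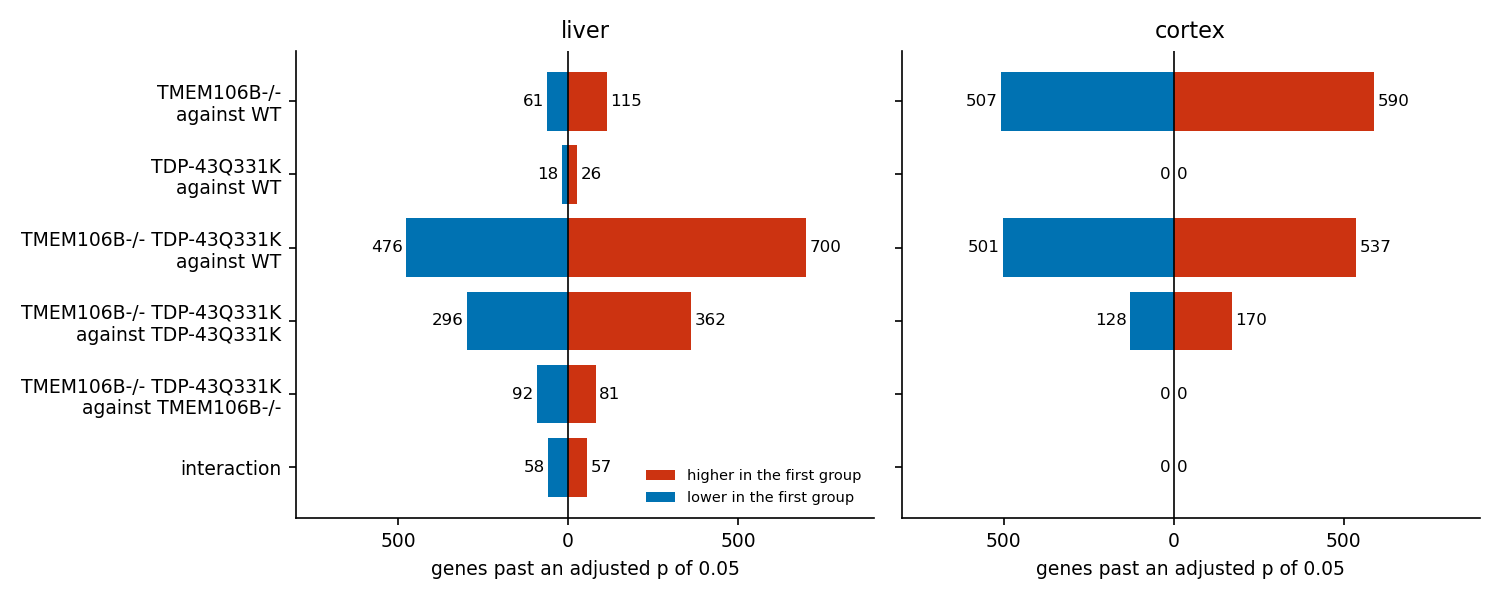
Genes past an adjusted p of 0.05 (edgeR) in each comparison, liver on the left and cortex on the right. Bars to the right count genes higher in the first group and bars to the left genes lower in it. The most were called in liver of the combined genotype against WT (700 higher, 476 lower) and in cortex of TMEM106B-/- against WT (590 higher, 507 lower).

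In liver, libraries labelled TMEM106B-/- were compared with WT to ask what TMEM106B loss does on a normal TDP-43 background. Of the fatty acid synthesis genes 7 of 18 rose, and of the cholesterol synthesis genes 6 of 25. Both lists lost their call with an estimated correlation (adjusted p = 0.0705 and adjusted p = 0.264). Scd1, the desaturase that makes monounsaturated fatty acids, was 3.26-fold higher (1.71 ± 0.27, adjusted p = 0.00525), and Acss2, which makes acetyl-CoA from acetate, was 3.63-fold higher (1.86 ± 0.24, adjusted p = 0.00129). Dhcr7, the reductase that ends cholesterol synthesis, was 2.32-fold higher (1.21 ± 0.15, adjusted p = 0.000521). Atp6v0e2, a subunit of the proton pump of lysosomes, was 7.88-fold higher (2.98 ± 0.30, adjusted p = 9.53e-05). Psmb5, a catalytic proteasome subunit, was 2.52-fold lower (-1.33 ± 0.14, adjusted p = 0.000141). Each group had 4 libraries. All 30 named genes that passed had 4 of 4 libraries beyond the WT mean, which is no separate evidence as they were named after passing. The same limit holds for each such count in the comparisons below, in liver and cortex. By edgeR 115 genes rose and 61 fell.

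Of the 18 fatty acid synthesis genes measured, 7 rose, none fell and the list moved up in 4 of 4 libraries (median 1.04, adjusted p = 2.57e-20). Adjusted over the list alone 11 rose, and the call was lost at adjusted p = 0.0705 with an estimated correlation. The elongase Elovl5 (1.51 ± 0.25) and malic enzyme Me1 (1.31 ± 0.25), a source of NADPH, were among them. Of 25 cholesterol synthesis genes 6 rose, or 15 adjusted over the list alone (median 0.75, adjusted p = 1.5e-17, 4 of 4 libraries; adjusted p = 0.264 with an estimated correlation). They included Nsdhl (0.99 ± 0.17), Acat2 (0.96 ± 0.19) and Lss (1.05 ± 0.22), the enzyme that closes the sterol rings. Of 26 fatty acid oxidation genes 1 rose, the peroxisomal enzyme Ehhadh (0.89 ± 0.18), or 2 adjusted over the list alone (adjusted p = 0.0236; adjusted p = 0.743 with an estimated correlation). The lipid droplet list had 0 members called over all genes and 3 adjusted over the list alone (median 0.12, adjusted p = 0.0277; adjusted p = 0.505 with an estimated correlation). Male-biased liver genes, known to be higher in males, moved down with 1 of 20 called, the transferase Gstp1 (-1.08 ± 0.17), or 5 adjusted over the list alone (median -0.23, adjusted p = 5.86e-05; adjusted p = 0.307 with an estimated correlation). Female-biased genes moved up with 0 called of 16 (median 1.55, adjusted p = 0.00271; adjusted p = 0.645 with an estimated correlation), and only 2 of the 4 libraries lay above the WT mean. Without the high acute phase livers, chosen after seeing the data, neither the oxidation list (adjusted p = 0.0681) nor the droplet list (adjusted p = 0.0642) passed. Of the other lists, 3 cholesterol synthesis genes and 1 female-biased gene rose then, and 3 male-biased genes fell (median -0.49).

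Markers of other cells moved in the same libraries. Endothelial markers moved down, with 1 of 13 called, the sinusoidal lectin Clec4g (-0.64 ± 0.14), or 3 adjusted over the list alone (median -0.33, adjusted p = 1.52e-05; adjusted p = 0.307 with an estimated correlation). Red blood cell genes moved down with 0 called, or 3 adjusted over the list alone (median -0.64, adjusted p = 0.000682; adjusted p = 0.265 with an estimated correlation). Outside the lists, Gstk1 (1.17 ± 0.12), Klhl33 (3.87 ± 0.51), Nuggc (3.64 ± 0.49) and Rdh11 (1.26 ± 0.19), a retinol dehydrogenase, rose. Cd207 (-2.74 ± 0.38), a lectin of Langerhans cells, Ajuba (-1.54 ± 0.21), Eva1a (-1.08 ± 0.15), Sertad4 (-3.20 ± 0.52) and Pck2 (-1.11 ± 0.17), the mitochondrial enzyme that makes phosphoenolpyruvate, fell. The count of 176 calls became 614 with DESeq2, 324 with limma-voom and 60 with only the compared groups in the fit. It became 353 without TMEM106B-/- replicate 4, 105 without replicate 1, 78 without replicate 2, 55 without replicate 3, 61 without WT replicate 2 and 77 without WT replicate 3.

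Liver libraries labelled TDP-43Q331K were compared with WT to ask what the Q331K change does alone. Few genes changed, 26 up and 18 down by edgeR, and another split of these libraries called 114. Ntrk2, the receptor of brain-derived neurotrophic factor, was 14.6-fold higher (3.87 ± 0.45, adjusted p = 0.00216), and Sult1e1, the estrogen sulfotransferase, was 123-fold higher (6.95 ± 0.93, adjusted p = 0.0103) from a low WT level. Reep5, a protein that shapes the endoplasmic reticulum, was 1.77-fold lower (-0.82 ± 0.12, adjusted p = 0.00532), and Hacl1, an enzyme of peroxisomal alpha-oxidation, was 3.23-fold lower (-1.69 ± 0.29, adjusted p = 0.0267). All 17 named genes that passed had 4 of 4 libraries beyond the WT mean.

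Markers of other cell types moved in these livers. Adipocyte markers moved up with 0 called of 5 (score 0.534 ± 0.346, SD, n = 4; list adjusted p = 0.0166; adjusted p = 0.499 with an estimated correlation). Endothelial markers moved down with 0 called of 13 (score -0.20 ± 0.0671; list adjusted p = 0.00727; adjusted p = 0.543 with an estimated correlation), as did red blood cell markers with 0 called of 5 (score -0.69 ± 0.294; list adjusted p = 0.00226; adjusted p = 0.499 with an estimated correlation). The fatty acid synthesis list moved up with 1 of 18 called, Acss2 (1.18 ± 0.24), or 8 adjusted over the list alone (median 0.61, adjusted p = 3.36e-09; adjusted p = 0.499 with an estimated correlation). Ribosomal protein genes moved down with 0 called, or 5 adjusted over the list alone (median -0.25, adjusted p = 3.06e-07; adjusted p = 0.543 with an estimated correlation). Kupffer cell markers also moved down with 0 called of 19, or 8 adjusted over the list alone (median -0.56, adjusted p = 4.5e-07; adjusted p = 0.499 with an estimated correlation), and endoplasmic reticulum stress genes moved down (median -0.71, adjusted p = 0.000658; adjusted p = 0.543 with an estimated correlation). All 4 libraries lay on the side of the list's direction in each. Targets of the xenobiotic receptors CAR and PXR moved up with 1 called, Aldh1a7 (0.67 ± 0.12; list adjusted p = 0.000738; adjusted p = 0.533 with an estimated correlation). Leaving out the high acute phase livers, chosen after seeing the data, left 0 genes called in the fatty acid synthesis list and in that of CAR and PXR, and moved the median of the stress genes to -0.33. Gstp3 (0.86 ± 0.14), Exoc4 (0.65 ± 0.12), a subunit of the exocyst, Wif1 (2.28 ± 0.43), a Wnt inhibitor, and Cyp2d12 (3.03 ± 0.58) rose. Slc17a1 (-1.15 ± 0.20), Cspg5 (-2.96 ± 0.53) and Map1lc3a (-0.56 ± 0.11), which coats autophagosomes, fell. The 44 calls became 391 with DESeq2, 341 with limma-voom, 20 with only the compared groups in the fit, 13 with the replicate block or 1 surrogate variable, and 12 without the high acute phase livers (chosen after seeing the data). They became 19, 8, 7 and 71 without WT replicates 1, 2, 3 and 4, and 10, 13, 26 and 7 without TDP-43Q331K replicates 1, 2, 3 and 4.

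The combined genotype was compared with WT in liver to ask what both changes do together. Hsd3b5, a steroid dehydrogenase of male liver, was 24.2-fold lower, at 8.10 ± 2.67 CPM against 196.4 ± 36.7 in WT (-4.60 ± 0.26, adjusted p = 7e-08). Mup20, which encodes the urinary pheromone darcin, was 5.53-fold lower (-2.47 ± 0.18, adjusted p = 5.53e-07). Cd36, a fatty acid transporter, was 5.36-fold higher (2.42 ± 0.19, adjusted p = 1.36e-06), and Cyp2b9, a cytochrome of female liver, was 228-fold higher, at 118.0 ± 37.9 CPM against 0.515 ± 0.369 (7.83 ± 0.86, adjusted p = 0.000171). Each group had 4 libraries, and all 44 named genes that passed had 4 of 4 beyond the WT mean. By edgeR 700 genes rose and 476 fell.

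Of 20 male-biased genes 14 fell, or 16 adjusted over the list alone (median -1.80, adjusted p = 1.34e-33), and the call held at adjusted p = 0.00114 with an estimated correlation. Gstp1 (-1.81 ± 0.18), Cyp7b1 (-1.79 ± 0.21), an oxysterol hydroxylase, and C6 (-1.84 ± 0.23), a complement component, were among them. Of 16 female-biased genes 9 rose, or 11 adjusted over the list alone (median 3.05, adjusted p = 5.88e-13; adjusted p = 0.044 with an estimated correlation). They included Hao2 (5.17 ± 0.67), Cyp2a4 (5.20 ± 0.83) and Cyp2b13 (5.92 ± 0.81). Of 23 lipid droplet genes 9 rose, or 11 adjusted over the list alone (median 0.75, adjusted p = 5.45e-15; adjusted p = 0.00114 with an estimated correlation). Mogat1, which makes diacylglycerol, was 8-fold higher (3.0 ± 0.34), and Vldlr (2.41 ± 0.42) and the droplet coat Plin3 (0.81 ± 0.15) also rose. Of 18 fatty acid synthesis genes 11 rose, or 14 adjusted over the list alone (median 1.27, adjusted p = 3.17e-20; adjusted p = 0.0317 with an estimated correlation), with Elovl5 (2.42 ± 0.26), Me1 (2.19 ± 0.25), Acss2 (1.96 ± 0.24) and Scd1 (1.81 ± 0.27). In these lists all 4 libraries lay apart from WT. Without the high acute phase livers, chosen after seeing the data, 13 male-biased genes fell. Then 8 female-biased, 9 lipid droplet and 10 fatty acid synthesis genes rose. The Mup, Cyp2a, Cyp2b and Cyp4a families have near-identical copies, so their single members are less certain, such as Cyp4a12b (-2.27) beside Cyp4a12a (0.16).

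**Figure D2:**
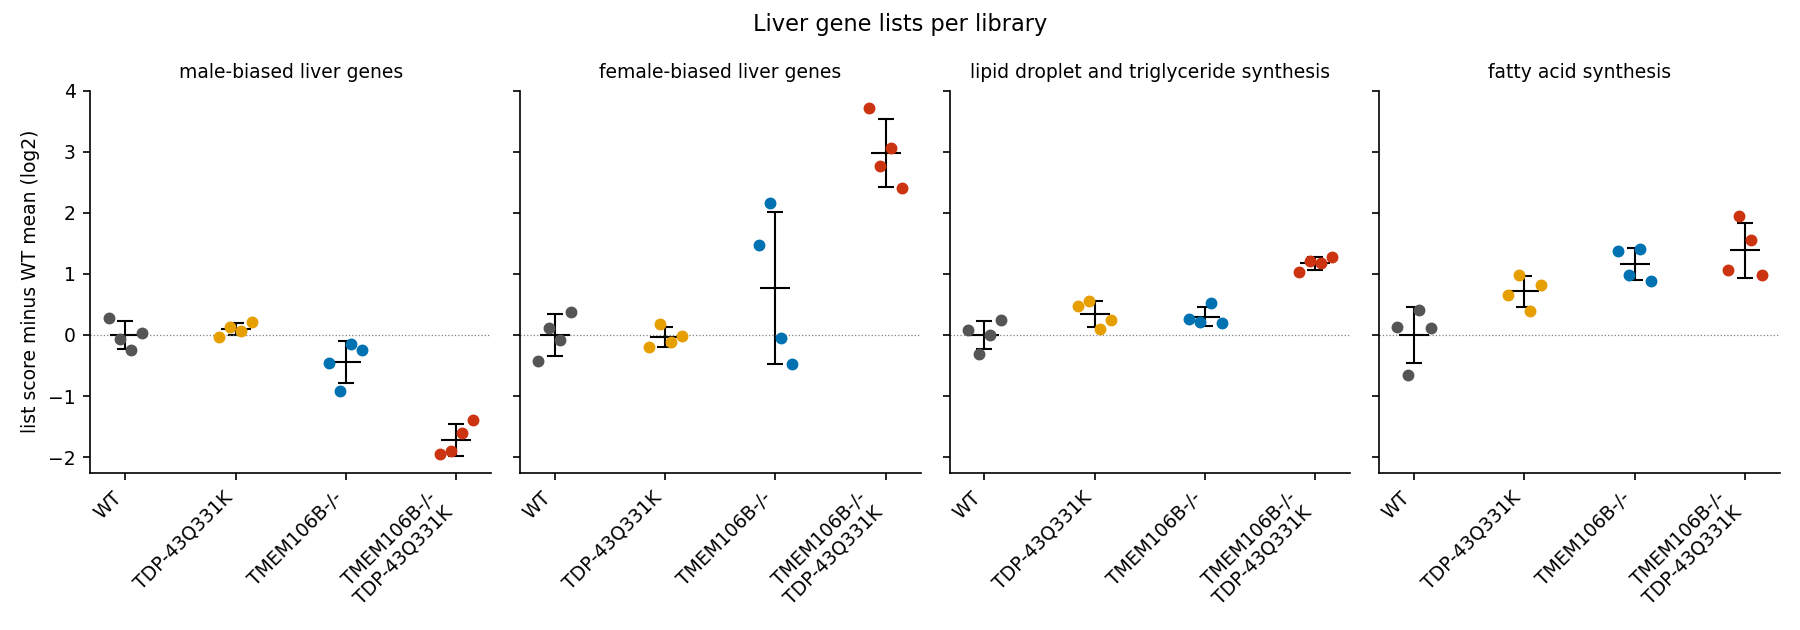
Liver scores (log2, minus the WT mean) of male-biased, female-biased, lipid droplet and fatty acid synthesis genes. Points are libraries (n = 4 per genotype) and bars the mean and SD. The 4 libraries of the combined genotype lie apart from the 4 WT libraries in each list.

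Other lists moved in the same livers. Of 25 cholesterol synthesis genes 9 rose, or 13 adjusted over the list alone, with Dhcr7 (1.27 ± 0.15) and Acat2 (1.19 ± 0.19) (list adjusted p = 2.86e-12; adjusted p = 0.227 with an estimated correlation). Of 26 fatty acid oxidation genes 11 rose, or 15 adjusted over the list alone (adjusted p = 1.5e-11; adjusted p = 0.227 with an estimated correlation), with Ehhadh (1.28 ± 0.18), Vnn1 (1.41 ± 0.27) and Pdk4 (1.53 ± 0.31), the kinase that restrains pyruvate dehydrogenase. Ribosomal protein genes moved down with 7 fallen, or 15 adjusted over the list alone, such as Rpl19 (-0.46 ± 0.12; list adjusted p = 1.52e-07; adjusted p = 0.447 with an estimated correlation). Stellate cell and fibrosis genes moved up with 5 risen, or 6 adjusted over the list alone, such as the collagens Col3a1 (1.22 ± 0.21) and Col1a1 (1.60 ± 0.30; list adjusted p = 5.78e-06; adjusted p = 0.246 with an estimated correlation). Of 48 lysosome genes 2 rose and 1 fell over all genes and over the list alone (median 0.18, adjusted p = 0.00169; adjusted p = 0.447 with an estimated correlation), with Atp6v0e2 (3.51 ± 0.30) and Ppt1 (0.37 ± 0.11) higher. Bile duct markers moved down with 0 called, or 2 adjusted over the list alone (median -0.63, adjusted p = 0.0166; adjusted p = 0.447 with an estimated correlation). Adipocyte markers moved up with 1 of 5 called, or 2 adjusted over the list alone (adjusted p = 0.0351; adjusted p = 0.407 with an estimated correlation). With the high acute phase livers left out, chosen after seeing the data, 6 oxidation and 3 ribosomal protein genes were called, the lysosome median was 0.12, and the bile duct list did not pass (adjusted p = 0.0995). Outside the lists Gpat3 (2.48 ± 0.25), which starts glycerolipid synthesis, Slc22a27 (3.58 ± 0.30), Tceal8 (2.55 ± 0.22) and Lgals1 (2.03 ± 0.21) rose, and Irf5 (-1.48 ± 0.13) and Lifr (-1.43 ± 0.18) fell. The 1176 calls became 1940 with limma-voom and 1847 with DESeq2. They became 762 without WT replicate 2, 755 without WT replicate 3, and 686 and 681 without replicates 2 and 3 of the combined genotype.

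The combined genotype was compared with TDP-43Q331K in liver to ask what TMEM106B loss does on the mutant background. Hsd3b5 was 20.4-fold lower (-4.35 ± 0.26, adjusted p = 1.12e-07) and Mup20 4.59-fold lower (-2.20 ± 0.18, adjusted p = 1.71e-06). Gpat3 was 7.87-fold higher (2.98 ± 0.25, adjusted p = 3.82e-06), Cd36 3.90-fold higher (1.96 ± 0.19, adjusted p = 9.72e-06) and Atp6v0e2 11.6-fold higher (3.53 ± 0.31, adjusted p = 3.96e-06). By edgeR 362 genes rose and 296 fell, with 4 libraries per group. All 40 named genes that passed had 4 of 4 libraries beyond the TDP-43Q331K mean.

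Of 20 male-biased genes 12 fell, or 15 adjusted over the list alone (median -1.26, adjusted p = 8.19e-39; adjusted p = 0.000938 with an estimated correlation), such as Cyp4a12b (-3.05 ± 0.30). Of 16 female-biased genes 11 rose, or 12 adjusted over the list alone (median 3.39, adjusted p = 1.63e-15; adjusted p = 0.0288 with an estimated correlation), such as Hao2 (4.80 ± 0.65) and Cyp2b9 (5.57 ± 0.75). Of 23 lipid droplet genes 7 rose, or 12 adjusted over the list alone (median 0.52, adjusted p = 1.98e-10; adjusted p = 0.00667 with an estimated correlation), such as Vldlr (3.11 ± 0.44), Mogat1 (1.94 ± 0.32) and the fatty acid carrier Fabp4 (1.05 ± 0.18). In fatty acid oxidation 6 rose, or 11 adjusted over the list alone (adjusted p = 1.7e-08; adjusted p = 0.255 with an estimated correlation), with Crat (1.15 ± 0.20), Vnn1 (1.53 ± 0.27) and Cyp4a14 (5.66 ± 0.99). In cholesterol synthesis 6 rose, or 8 adjusted over the list alone (adjusted p = 6.94e-08; adjusted p = 0.31 with an estimated correlation), with Hmgcs1 (1.64 ± 0.35) and Mvd (1.57 ± 0.33). In fatty acid synthesis Elovl5 (1.56 ± 0.25) and Me1 (1.26 ± 0.24) rose, or 8 genes adjusted over the list alone (adjusted p = 1.48e-06; adjusted p = 0.255 with an estimated correlation). After removal of the high acute phase livers, chosen after seeing the data, 3 cholesterol synthesis, 9 oxidation and 4 fatty acid synthesis genes rose.

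Cell type and stress lists moved with these. Kupffer cell markers moved up with 1 called, Cd9 (1.53 ± 0.23), or 5 adjusted over the list alone (adjusted p = 1.88e-05; adjusted p = 0.312 with an estimated correlation). Stellate and fibrosis genes moved up with 3 called, Col1a2 (0.89 ± 0.19), Col3a1 (0.88 ± 0.20) and Timp1 (1.88 ± 0.50), or 6 adjusted over the list alone (adjusted p = 1.77e-06; adjusted p = 0.255 with an estimated correlation). NRF2 targets moved up with 3 called, Hmox1 (1.10 ± 0.21), Gsta1 (2.51 ± 0.50) and Nqo1 (1.18 ± 0.30), or 4 up and 1 down adjusted over the list alone (adjusted p = 2.06e-05; adjusted p = 0.206 with an estimated correlation). Of the lysosome genes 5 rose, or 6 adjusted over the list alone, such as Cd63 (1.17 ± 0.24) and the protease Ctsd (0.45 ± 0.11; list adjusted p = 0.000168; adjusted p = 0.31 with an estimated correlation). Gstk1 (1.32 ± 0.12), Ephb6 (3.88 ± 0.37) and Nuggc (2.75 ± 0.50) rose, and Irf5 (-1.36 ± 0.13), Clic5 (-2.10 ± 0.30), Ajuba (-1.40 ± 0.21), Gstp1 (-1.42 ± 0.18) and Ints7 (-0.89 ± 0.18) fell. The 658 calls became 1865 with limma-voom and 1309 with DESeq2. They became 380 and 291 without TDP-43Q331K replicates 3 and 4, and 408, 248 and 388 without replicates 1, 2 and 3 of the combined genotype.

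The combined genotype was compared with TMEM106B-/- in liver to ask what Q331K adds once TMEM106B is labelled lost. Hsd3b5 was 15.2-fold lower (-3.93 ± 0.26, adjusted p = 5.06e-07) and Mup20 3.87-fold lower (-1.95 ± 0.17, adjusted p = 1.55e-05). Cd36 was 3.23-fold higher (1.69 ± 0.18, adjusted p = 0.000136) and Gpat3 5.30-fold higher (2.41 ± 0.25, adjusted p = 7.01e-05). By edgeR 81 genes rose and 92 fell. All 19 named genes that passed had 4 of 4 libraries beyond the TMEM106B-/- mean. Of 20 male-biased genes 8 fell, or 14 adjusted over the list alone (median -1.04, adjusted p = 8.27e-30; adjusted p = 0.00194 with an estimated correlation), such as Cyp4a12b (-2.51 ± 0.30). Of 23 lipid droplet genes 3 rose, or 11 adjusted over the list alone (median 0.46, adjusted p = 5.55e-15; adjusted p = 0.00194 with an estimated correlation), namely Cd36, Mogat1 (2.06 ± 0.32) and Pparg (0.95 ± 0.21), a receptor that drives fat storage. Female-biased genes moved up with 5 called, or 10 up and 1 down adjusted over the list alone (median 1.89, adjusted p = 2.86e-10; adjusted p = 0.057 with an estimated correlation), such as Cyp2b9 (7.46 ± 0.84) and Cyp2a4 (4.65 ± 0.80). Without the high acute phase livers, chosen after seeing the data, the female-biased median was 0.70 with 4 called, and 4 male-biased genes fell (median -0.77). Fatty acid oxidation genes moved up with 3 called, Vnn1 (1.55 ± 0.27), Crat (0.98 ± 0.20) and Pdk4 (1.44 ± 0.31), or 11 adjusted over the list alone (adjusted p = 2.75e-09; adjusted p = 0.292 with an estimated correlation). Endothelial markers moved up with 0 called (median 0.33, adjusted p = 3.83e-05; adjusted p = 0.292 with an estimated correlation), and clock genes moved down with 1 called, Bhlhe41 (-1.67 ± 0.35; list adjusted p = 0.0328; adjusted p = 0.18 with an estimated correlation). Without the high acute phase livers 1 oxidation gene and 0 clock genes were called. Cholesterol synthesis did not pass (adjusted p = 0.882). Tceal8 (2.22 ± 0.22), Slc22a27 (2.45 ± 0.29), Gsta1 (2.55 ± 0.50) and Exoc4 (0.65 ± 0.12) rose, and Irf5 (-1.01 ± 0.13) fell. The 173 calls became 531 with DESeq2, 376 with limma-voom, 304 with 1 surrogate variable and 81 with only the compared groups in the fit. They became 104 and 101 without TMEM106B-/- replicates 1 and 2, and 77 and 98 without replicates 2 and 3 of the combined genotype.

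The interaction in liver tested whether the effect of labelled TMEM106B loss differed between the TDP-43 backgrounds. By edgeR 57 genes had a more positive and 58 a more negative effect with Q331K. The difference was -3.68 ± 0.33 for Hsd3b5 (adjusted p = 6.88e-05), -1.68 ± 0.24 for Mup20 (adjusted p = 0.00385) and -3.29 ± 0.41 for Cyp4a12b (adjusted p = 0.00193). It was 2.91 ± 0.35 for Gpat3 (adjusted p = 0.00101), 2.47 ± 0.30 for Tceal8 (adjusted p = 0.00116) and 1.23 ± 0.25 for Cd36 (adjusted p = 0.0327), with 4 libraries in each genotype. Male-biased genes differed downwards with 5 of 20 called, or 12 adjusted over the list alone (median -0.87, adjusted p = 7.45e-16; adjusted p = 0.0416 with an estimated correlation). Female-biased genes differed upwards with 2 called, or 5 adjusted over the list alone (median 2.41, adjusted p = 2.57e-06; adjusted p = 0.177 with an estimated correlation). When the high acute phase livers were left out, chosen after seeing the data, the female-biased median was 1.15 with 0 called and 3 male-biased genes were called (median -0.73). Lipid droplet genes differed upwards with 1 called, or 6 up and 1 down adjusted over the list alone (median 0.31, adjusted p = 0.000525; adjusted p = 0.156 with an estimated correlation). Fatty acid synthesis differed downwards with 0 called (median -0.29, adjusted p = 0.0231; adjusted p = 0.669 with an estimated correlation), and did not pass without the high acute phase livers (median -0.19, adjusted p = 0.136). Endothelial and Kupffer cell markers differed upwards (adjusted p = 2.57e-06 and adjusted p = 5.42e-06) with 0 called in either, and adjusted over the list alone 7 and 1 (adjusted p = 0.177 and adjusted p = 0.329 with an estimated correlation). The 115 calls became 597 with DESeq2 and 320 with limma-voom. They became 68, 76, 76 and 65 without TDP-43Q331K replicates 1 to 4, 189 without TMEM106B-/- replicate 4 and 51 without replicate 2 of the combined genotype.

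In cortex, libraries labelled TMEM106B-/- were compared with WT. Genes of myelin fell together. Aspa, the aspartoacylase of oligodendrocytes, was 1.99-fold lower (-0.996 ± 0.115, adjusted p = 6.06e-05), and Ugt8a, which makes the myelin lipid galactosylceramide, was 2.22-fold lower (-1.15 ± 0.14, adjusted p = 0.000126). Mbp, which encodes myelin basic protein, was at 601.5 ± 96.6 CPM (SD, n = 5) against 1405 ± 111 in WT (n = 5). Cav2, a caveolin, was 1.67-fold lower (-0.74 ± 0.07, adjusted p = 1.68e-06), and Met, a growth factor receptor, was 1.53-fold higher (0.61 ± 0.09, adjusted p = 0.000217). By edgeR 590 genes rose and 507 fell. Of 44 named genes that passed, 43 had 5 of 5 libraries beyond the WT mean.

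Of 26 myelin genes 25 fell, over all genes and adjusted over the list alone (median -1.23, adjusted p = 5.04e-70, 5 of 5 libraries), and the call held at adjusted p = 0.00846 with an estimated correlation. Others among them were Tspan2 (-1.08 ± 0.13) and the transcription factor Nkx6-2 (-1.37 ± 0.18). Abca8a (-1.15 ± 0.13), Tmem98 (-1.07 ± 0.13) and the choline transporter Slc44a1 (-0.42 ± 0.04) also fell. Markers of neighbouring tissue moved in the same libraries. The meninges score was 1.20 ± 0.58 (SD, n = 5) above the WT mean, the deep cortical layer score was at -0.65 ± 0.54 and the upper layer score at 0.30 ± 0.26, where the WT libraries had SDs of 0.581, 0.143 and 0.13. Of 15 meninges genes 11 rose, or 13 adjusted over the list alone, such as Col3a1 (1.71 ± 0.41), Col1a1 (1.76 ± 0.41), Bmp6 (1.38 ± 0.31) and Ptgds (1.46 ± 0.34; list adjusted p = 4.75e-12; adjusted p = 0.35 with an estimated correlation). Without the cortices with extreme markers, chosen after seeing the data, 0 meninges genes (median 1.01) and 23 myelin genes (median -1.13) were called. Striatum markers moved down with 0 called, such as Drd2 at -1.86 ± 0.72 (list adjusted p = 0.00349; adjusted p = 0.52 with an estimated correlation).

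**Figure D3:**
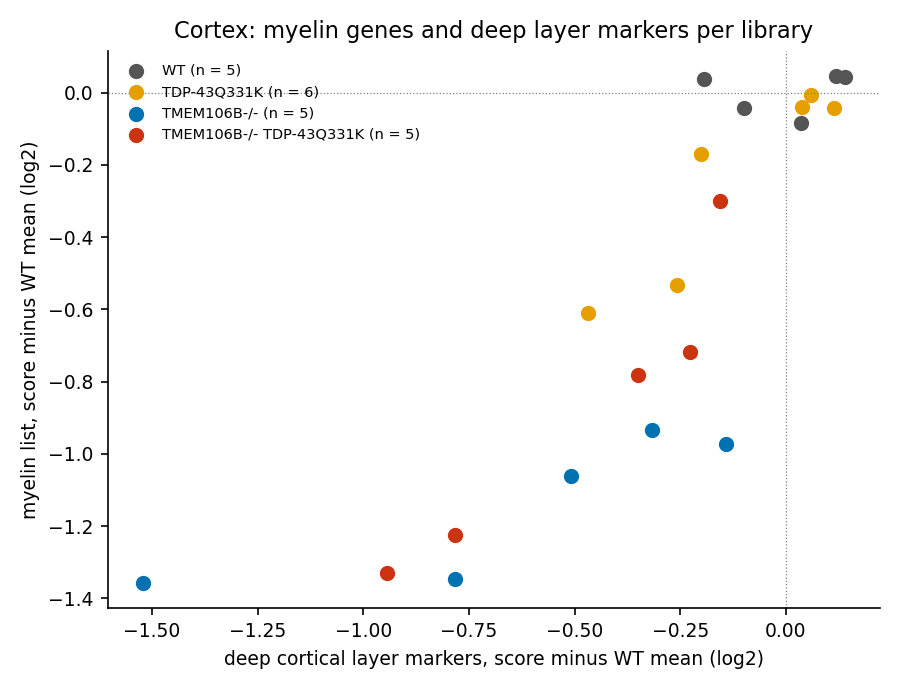
Myelin list score against the score of deep cortical layer markers in each of the 21 cortex libraries (log2, minus the WT mean), coloured by genotype. The TMEM106B-/- libraries (n = 5) lie lower on both axes than the WT libraries (n = 5) on average.

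Cholesterol synthesis moved down with 1 of 25 called, Stard4 (-0.33 ± 0.07), or 2 adjusted over the list alone (median -0.18, adjusted p = 1.02e-06; adjusted p = 0.363 with an estimated correlation). Fatty acid synthesis moved down with Scd1 (-0.47 ± 0.05) and Scd2 (-0.24 ± 0.04) called (list adjusted p = 0.0145; adjusted p = 0.363 with an estimated correlation). Reactive astrocyte genes moved up with 2 called, Serping1 (1.25 ± 0.34) and Cp (0.54 ± 0.15), or 7 adjusted over the list alone (adjusted p = 0.000117; adjusted p = 0.35 with an estimated correlation). Vessel markers moved up with 3 called, Vtn (0.56 ± 0.10), Cdh5 (0.54 ± 0.11) and Pdgfrb (0.26 ± 0.06), or 7 adjusted over the list alone (adjusted p = 0.000156; adjusted p = 0.363 with an estimated correlation). Genes of disease-associated microglia moved up with 3 called, including Cd68 (0.39 ± 0.08) and Spp1 (0.97 ± 0.25; list adjusted p = 0.041; adjusted p = 0.515 with an estimated correlation). For Spp1, 4 of 5 libraries lay above the WT mean. Interferon genes moved up with 2 called, Oasl2 (0.74 ± 0.17) and Gbp2 (0.70 ± 0.19; list adjusted p = 0.041; adjusted p = 0.52 with an estimated correlation). Outside the lists Npl (1.16 ± 0.17), Sphk1 (1.41 ± 0.21), Pm20d1 (0.99 ± 0.16), F2rl2 (0.72 ± 0.10) and Cpne6 (0.52 ± 0.07) rose, and Trbc2 (-2.53 ± 0.33) and Tatdn3 (-0.83 ± 0.11) fell. With deep layer, striatum and meninges scores as covariates, chosen after seeing the data, 48 genes were called and the myelin median was -0.77 with 5 called (adjusted p = 0.0661 with an estimated correlation). Under these covariates the 6 lists named before in this paragraph did not pass. Cholesterol synthesis was at a median of -0.05 with 0 called (adjusted p = 0.206), fatty acid synthesis at -0.04 with 1 called (adjusted p = 0.17) and reactive astrocyte genes at 0.01 with 0 called (adjusted p = 0.675). The direction turned for vessel markers (adjusted p = 0.92), disease-associated microglia (adjusted p = 0.955) and interferon genes (adjusted p = 0.955), each with 0 called, and for Serping1 (-0.08), Cp (-0.0048) and Spp1 (-0.09). Without the cortices with extreme markers the microglia (adjusted p = 0.271) and interferon (adjusted p = 0.259) lists did not pass either. With limma-voom 1689 were called, and 707, 700 and 664 without WT replicate 3, WT replicate 4 and TMEM106B-/- replicate 1.

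Cortex libraries labelled TDP-43Q331K (n = 6) were compared with WT (n = 5). Cholesterol synthesis genes were lower as a group, by little each. All 25 had negative log2 fold changes (median -0.23), the list moved down (adjusted p = 1.74e-36, 6 of 6 libraries), and the call held at adjusted p = 0.0137 with an estimated correlation. No gene passed over all genes by edgeR, and 19 of these 25 passed adjusted over the list alone. Nsdhl stood at -0.25 ± 0.06 (adjusted p = 0.415), Msmo1 at -0.28 ± 0.07 (adjusted p = 0.415) and Stard4, a sterol carrier, at -0.28 ± 0.07 (adjusted p = 0.431).

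The fatty acid synthesis list moved down with 0 called, or 3 adjusted over the list alone (median -0.07, adjusted p = 0.000188; adjusted p = 0.0937 with an estimated correlation), and Fads2 stood at -0.21 ± 0.05. All 26 myelin genes had negative values with 0 called (median -0.23, adjusted p = 4.73e-10; adjusted p = 0.884 with an estimated correlation), and Aspa stood at -0.30 ± 0.11. Reactive astrocyte genes moved up with 0 called, or 2 adjusted over the list alone (adjusted p = 0.00572; adjusted p = 0.884 with an estimated correlation), and did not pass with the marker scores as covariates (adjusted p = 0.18) or without the cortices with extreme markers (adjusted p = 0.0848). Of the 21248 genes 1036 had an unadjusted p under 0.05, and against the 0 calls of edgeR DESeq2 called 3, limma-voom 11 and edgeR with only the compared groups 2. Without the cortices with extreme markers, chosen after seeing the data, edgeR called 2, and with the replicate block 1.

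The combined genotype was compared with WT in cortex. Ugt8a was 1.84-fold lower (-0.88 ± 0.14, adjusted p = 0.00322), Aspa 1.58-fold lower (-0.66 ± 0.11, adjusted p = 0.00442) and Cav2 1.65-fold lower (-0.72 ± 0.07, adjusted p = 3.03e-06). Pm20d1, an enzyme that makes N-acyl amino acids, was 2.30-fold higher (1.20 ± 0.15, adjusted p = 0.000393), and Angptl4, an inhibitor of lipoprotein lipase, was 2.63-fold higher (1.39 ± 0.24, adjusted p = 0.00402). By edgeR 537 genes rose and 501 fell, with 5 libraries per group. All 36 named genes that passed had 5 of 5 libraries beyond the WT mean.

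Of 26 myelin genes 23 fell, or 25 adjusted over the list alone (median -0.88, adjusted p = 4.72e-41; adjusted p = 0.0834 with an estimated correlation), such as Qdpr (-0.69 ± 0.10) and Nkx6-2 (-0.97 ± 0.18). The meninges score in these libraries was 1.08 ± 0.30 (SD, n = 5) above the WT mean, the deep layer score was at -0.49 ± 0.35 and the upper layer score at 0.38 ± 0.17. Meninges genes moved up with 3 called, or 13 adjusted over the list alone, such as Bmp6 (1.35 ± 0.31) and Ptgds (1.41 ± 0.34; list adjusted p = 2.04e-09; adjusted p = 0.242 with an estimated correlation). Cholesterol synthesis moved down with 3 called, Stard4 (-0.46 ± 0.07), Hmgcs1 (-0.35 ± 0.08) and Acat2 (-0.26 ± 0.07), or 15 adjusted over the list alone (median -0.19, adjusted p = 2.87e-10; adjusted p = 0.242 with an estimated correlation). Immediate early genes, known to respond to neuronal activity, moved up with 3 called, Nr4a2 (1.26 ± 0.25), Fosl2 (0.89 ± 0.19) and Egr2 (1.83 ± 0.44; list adjusted p = 3.82e-06; adjusted p = 0.417 with an estimated correlation). Reactive astrocyte genes moved up with 2 called, Osmr (0.63 ± 0.14) and Cp (0.65 ± 0.15), or 7 adjusted over the list alone (adjusted p = 7.68e-06; adjusted p = 0.235 with an estimated correlation). Genes of disease-associated microglia moved up with 3 called, Cd68 (0.44 ± 0.08), B2m (0.44 ± 0.08) and Spp1 (1.23 ± 0.25), or 5 adjusted over the list alone (adjusted p = 0.00212; adjusted p = 0.242 with an estimated correlation). Inhibitory neuron genes moved up with 1 called, Gad2 (0.20 ± 0.05), or 8 up and 1 down adjusted over the list alone (adjusted p = 0.00117; adjusted p = 0.235 with an estimated correlation). Chil1 (0.74 ± 0.12), Rnase4 (0.83 ± 0.14), Met (0.62 ± 0.09) and Sphk1 (1.28 ± 0.21) rose, and Trbc2 (-2.30 ± 0.32), Hsp90aa1 (-0.23 ± 0.04), a chaperone, and Slc44a1 (-0.27 ± 0.04) fell. With the marker scores as covariates, chosen after seeing the data, 9 genes were called and the myelin median was -0.55 with 0 called (adjusted p = 0.201 with an estimated correlation). No gene of the other lists of this paragraph was called then, and the meninges (adjusted p = 0.68), reactive astrocyte (adjusted p = 0.0771) and microglia (adjusted p = 0.188) lists did not pass. The cholesterol synthesis median was -0.12 and that of inhibitory neuron genes 0.11. The 1038 calls became 1818 with limma-voom, 1601 with DESeq2 and 428 with 1 surrogate variable, and 508, 487, 436, 487 and 422 without WT replicates 2, 3 and 4 and replicates 3 and 4 of the combined genotype.

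The combined genotype (n = 5) was compared with TDP-43Q331K (n = 6) in cortex. Cav2 was 1.65-fold lower (-0.72 ± 0.06, adjusted p = 8.58e-07) and Met 1.5-fold higher (0.59 ± 0.08, adjusted p = 0.000825). Among myelin genes Ugt8a was 1.55-fold lower (-0.63 ± 0.13, adjusted p = 0.0282) and Qdpr, which recycles tetrahydrobiopterin, 1.35-fold lower (-0.43 ± 0.09, adjusted p = 0.0283). By edgeR 170 genes rose and 128 fell. All 24 named genes that passed had 5 of 5 libraries beyond the TDP-43Q331K mean.

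Of 26 myelin genes 6 fell, or 24 adjusted over the list alone (median -0.64, adjusted p = 1.5e-27; adjusted p = 0.188 with an estimated correlation), including Nkx6-2 (-0.73 ± 0.17). No myelin gene was called without the cortices with extreme markers (median -0.48) or with the marker scores as covariates (median -0.38; adjusted p = 0.283 with an estimated correlation), settings chosen after seeing the data. The deep layer score was at -0.49 ± 0.35 in these libraries and at -0.12 ± 0.23 in TDP-43Q331K (SD, n = 6), and the meninges scores were 1.08 ± 0.30 and 0.31 ± 0.47. Meninges genes moved up with 0 called, or 9 adjusted over the list alone (median 0.84, adjusted p = 4.53e-07; adjusted p = 0.406 with an estimated correlation), with Ptgds at 1.18 ± 0.32 (adjusted p = 0.07). Immediate early genes moved up with Nr4a2 (1.21 ± 0.23) and Egr2 (1.88 ± 0.42) called, or 7 adjusted over the list alone (median 0.54, adjusted p = 1.62e-07; adjusted p = 0.406 with an estimated correlation). Inhibitory neuron genes moved up with 0 called, or 8 up and 1 down adjusted over the list alone (adjusted p = 0.000395; adjusted p = 0.188 with an estimated correlation). Genes of disease-associated microglia moved up with 2 called, B2m (0.36 ± 0.08) and Spp1 (0.97 ± 0.23), or 4 adjusted over the list alone (adjusted p = 0.0112; adjusted p = 0.406 with an estimated correlation). RNA processing genes moved down with 1 called, the TDP-43 relative Hnrnpa1 (-0.36 ± 0.08), or 1 up and 4 down adjusted over the list alone (adjusted p = 0.0291; adjusted p = 0.406 with an estimated correlation). With the marker scores as covariates the meninges (adjusted p = 0.695), microglia (adjusted p = 0.173) and RNA processing (adjusted p = 0.0545) lists did not pass, 0 immediate early genes were called and the median of inhibitory neuron genes was 0.11. Pm20d1 (1.03 ± 0.14), Kit (0.41 ± 0.06), Cpne6 (0.42 ± 0.07) and Chil1 (0.69 ± 0.11) rose, and Tatdn3 (-0.75 ± 0.10), Trbc2 (-2.13 ± 0.32), Clic5 (-0.53 ± 0.10) and Bag1 (-0.43 ± 0.08) fell. The 298 calls became 819 with DESeq2, 781 with limma-voom, 104 with only the compared groups, 171, 120 and 175 with no filter, the replicate block and 1 surrogate variable, and, chosen after seeing the data, 131 without the cortices with extreme markers and 17 with the marker scores as covariates. They became 53, 94, 119 and 87 without TDP-43Q331K replicates 1, 3, 4 and 5, and 148, 122, 59 and 1103 without replicates 1, 3, 4 and 5 of the combined genotype.

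The combined genotype and TMEM106B-/- (n = 5 each) were compared in cortex to ask what Q331K adds. No gene was called by edgeR, DESeq2 or limma-voom, and 1053 genes had an unadjusted p under 0.05 by edgeR. Myelin genes lay higher as a group, with 24 of 26 positive (median 0.33, adjusted p = 1.73e-10; adjusted p = 0.852 with an estimated correlation), in 3 of 5 libraries, and Aspa stood at 0.33 ± 0.12. Interferon genes lay lower (median -0.20, adjusted p = 0.00222; adjusted p = 0.852 with an estimated correlation), in 4 of 5 libraries, with Mx1, an antiviral GTPase, at -1.05 ± 0.34 (adjusted p = 0.97). With the marker scores as covariates, chosen after seeing the data, the medians were 0.19 for myelin and -0.10 for interferon genes.

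The interaction in cortex called 0 genes by edgeR, DESeq2 and limma-voom, with 972 at an unadjusted p under 0.05 by edgeR, so no single gene's effect of labelled TMEM106B loss was shown to differ between the backgrounds. As groups, all 26 myelin genes (median 0.54, adjusted p = 3.84e-21) and all 25 cholesterol synthesis genes (median 0.17, adjusted p = 3.44e-12) had positive interaction values, each at adjusted p = 0.207 with an estimated correlation. Adjusted over the list alone 1 gene passed in each. Interferon genes differed downwards (median -0.40, adjusted p = 2.93e-05; adjusted p = 0.207 with an estimated correlation), with Mx1 at -2.02 ± 0.47 (adjusted p = 0.715) and 1 gene passing adjusted over the list alone. Aspa stood at 0.64 ± 0.16 (adjusted p = 0.853). Without TMEM106B-/- replicate 5 or without replicate 4 of the combined genotype 1 gene was called, and 2 without the cortices with extreme markers, chosen after seeing the data.

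Effects of labelled TMEM106B loss on the WT and TDP-43Q331K backgrounds were compared across genes, which are not independent replicates. In cortex 82 genes rose and 69 fell in both (4.72 and 3.05 expected from independent calls, 0 opposite). Pearson r was 0.68 and Spearman rho 0.50 over 21248 genes. Both cortex groups labelled TMEM106B-/- shared a shift in tissue markers, so this overlap does not separate genotype from dissection. In liver 32 rose and 14 fell in both (2.49 and 1.08 expected, 0 opposite), with r = 0.26 and rho = 0.05 over 16710 genes. For Q331K on both TMEM106B backgrounds in liver, Exoc4 rose in both, 2 genes fell in both and 1 went opposite ways (r = -0.03, rho = -0.09). In cortex no gene was called in either of those comparisons (r = 0.05, rho = 0.03). Between tissues, of 14635 genes tested in both, 11 were called in the same direction in TMEM106B-/- against WT (3.95 expected, 6 opposite). They included Pm20d1 (1.13 ± 0.22 in liver, 0.99 ± 0.16 in cortex), Smyd2 (0.93 ± 0.14 and 0.30 ± 0.05), Gstm2 (1.13 ± 0.23 and 1.45 ± 0.28), Ide (0.90 ± 0.19 and 0.50 ± 0.14), which degrades insulin, and Tmem260 (-0.49 ± 0.10 and -0.40 ± 0.07). In the combined genotype against WT 37 were (25.3 expected, 27 opposite), with Tcn2 (0.75 ± 0.13 and 0.41 ± 0.10), Loxl2 (1.41 ± 0.24 and 1.41 ± 0.36) and Ints7 (-0.72 ± 0.18 and -0.47 ± 0.10). In the combined genotype against TDP-43Q331K 9 were (3.93 expected, 3 opposite).

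Genes called on both TDP-43 backgrounds were most dense in the part of chromosome 6 that holds Tmem106b and in a part of chromosome 14. Over both tissues there were 196 such genes, 1 of them called in both, and mt-Tp of the mitochondrial genome is left out below. Of the other 195, on chromosomes 1 to 19 and X, 36 were on chromosome 6, where 10.9 were expected from the number of tested genes, and 22 lay between positions 1 and 53089269 of that chromosome, within 40 Mb of Tmem106b, where 3.12 were expected. In liver Atp6v0e2, Gstk1, Ephb6 and St7 (0.87 ± 0.13) rose there, and in cortex Met rose and Cav2 and Trbc2 fell. Chromosome 14 held 18 where 6.57 were expected, and 17 of them, starting between positions 47240944 and 79288756, lay within 373 neighbouring tested genes (3.12 expected). Of these 17, 8 rose and 9 fell, among them Nuggc and Ajuba in liver and Tmem260 and Cpne6 in cortex. The 4 tested genes nearest to Tmem106b, Phf14, Thsd7a, Tmem168 and Bmt2, were not called by edgeR in the comparisons examined in either tissue, the lowest adjusted p being 0.116 for Bmt2 in cortex (TMEM106B-/- against WT, -0.15 ± 0.05). Both regions were examined after their genes had been seen.

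**Figure D4:**
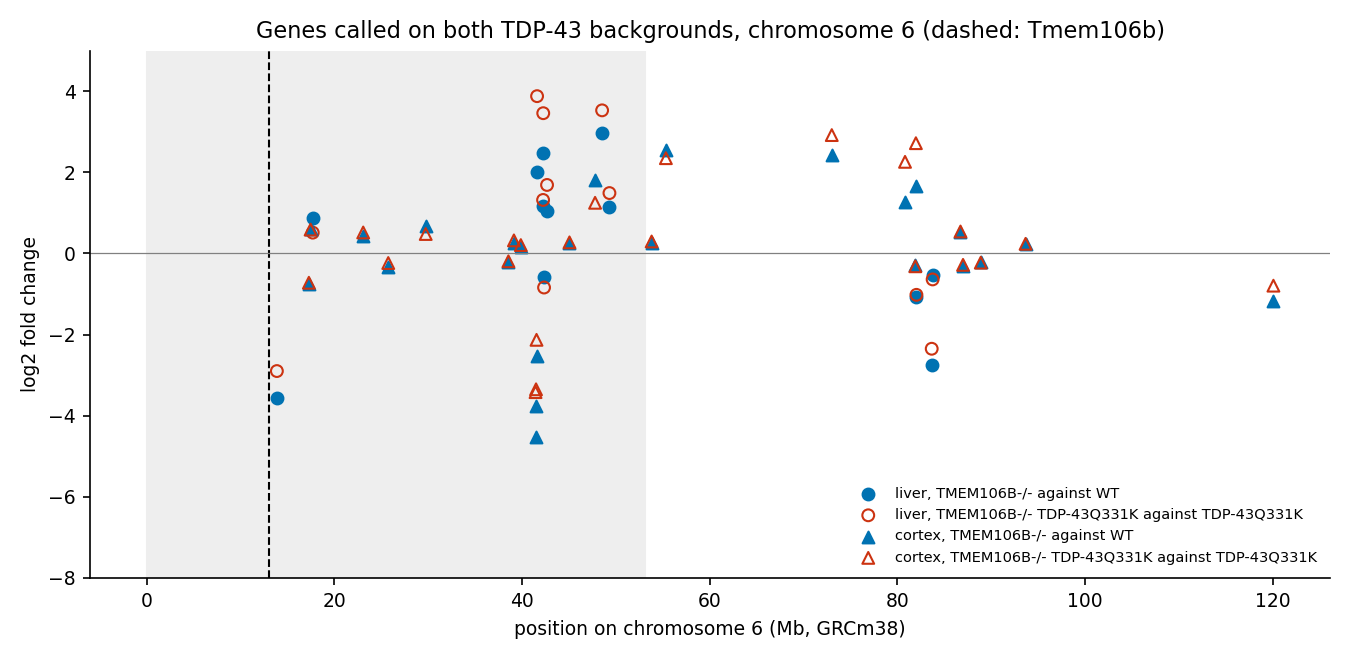
Log2 fold changes of chromosome 6 genes called on both TDP-43 backgrounds against their position (Mb, GRCm38), filled for TMEM106B-/- against WT and open for the combined genotype against TDP-43Q331K, circles for liver and triangles for cortex. The shaded window holds 22 of the 36 genes and the dashed line marks Tmem106b.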

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

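The tests of Xist, of the deep layer markers, of Pdgfra and of the region near Tmem106b were chosen only after the result was seen. The test of reads shared within gene families and that of the acute phase livers were chosen before, although these livers were picked out after seeing the data.

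In liver of the combined genotype, male-biased genes fell and female-biased genes rose against WT. Female animals in the group are argued against by the highest Xist level in these 4 libraries, 0.124 CPM. Reads shared between near-identical family members are argued against as the whole source, since 5 of the 9 male-biased genes outside the named families fell, of 14 fallen among 20 in all. The 3 livers with an acute phase response are argued against as the source, since 13 male-biased genes fell without them. A candidate explanation is an effect of the combined genotype on the hormonal control of liver genes, a hypothesis that came from these libraries and was not tested, since hormones were not measured here.

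In cortex of libraries labelled TMEM106B-/-, myelin genes fell against WT with a median of -1.23. A loss of the whole oligodendrocyte lineage is argued against by the precursor marker Pdgfra (0.05 ± 0.08 SE, value 0.0546). Meninges also hold Pdgfra and their score was 1.20 higher, but Pdgfra stood at -0.04 ± 0.08 with that score among the covariates and the precursor gene Lhfpl3 at 0.03 ± 0.10, while Olig1 (-0.48 ± 0.08), Enpp6 (-1.38 ± 0.26) and Bcas1 (-1.07 ± 0.16) fell. A tissue piece with less of the deep layers and white matter stays open. With the 3 scores the myelin median went from -1.23 to -0.77 (SD over members 0.221), all 26 values were negative and 5 genes were called. The list's adjusted p with an estimated correlation was 0.0661, against 0.00846 without them. The scores differed between genotypes and why the call ended was not tested, so dissection and an effect of labelled TMEM106B loss cannot be told apart.

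Genes called on both TDP-43 backgrounds were dense near Tmem106b, with 22 in a window of 373 tested genes against 3.12 expected. A chance position is argued against, since 0 percent of 15468 windows of as many genes elsewhere held as many, yet a region of chromosome 14, which is not linked to Tmem106b, held 17 against 3.12 expected. Reads lost to variants of another strain stay open for the 14 genes that rose and the 8 that fell. Which group carried such variants was not tested. DNA of another strain kept beside the edited gene cannot be told apart from an effect of the edit, because both follow the TMEM106B label, so the calls in liver comparisons with the same label (1.56 times an even spread, 5 against 3.21) cannot separate them. Past the window near Tmem106b, 373 more genes of chromosome 6 held 12 against 3.12 expected. The source of this excess or that on chromosome 14 was not tested.

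Tmem106b was not called lower by edgeR in libraries labelled TMEM106B-/- against WT, in liver (115.3 ± 9.32 CPM against 96.5 ± 16.3, SD, n = 4) or cortex (184.2 ± 6.66 CPM against 188 ± 4.69, n = 5; -0.03 ± 0.04 SE, adjusted p = 0.774). RNA counts cannot tell a loss that leaves the RNA from wrong labels, and neither was tested.

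Some libraries lay far from the others of their group for a named gene, which is judged by the gap to the nearest library divided by the group's range (Dixon's ratio, given here). There were 38 such cases in 708 groups tested (5.37%), and chance gives about 1 in 20. In WT liver they were Crat (0.836, low) and Scd1 (0.878, high) in replicate 1 and Gstp1 (0.857, low) in replicate 4. In TDP-43Q331K liver they were Ajuba in replicate 2 (0.851, low) and Gstk1 in replicate 4 (0.954, low). In TMEM106B-/- liver they were Pck2 (0.958, high) and Scd1 (0.907, low) in replicate 1, Smyd2 in replicate 2 (0.863, high), and Cd36 (0.856, low) and Timp1 (0.907, high) in replicate 4. In liver of the combined genotype they were Lifr in replicate 1 (0.839, high), Renbp (0.844, high) and Wfdc2 (0.856, high) in replicate 2, Capn8 (0.925, high) and Ntrk2 (0.873, high) in replicate 3, and Lss (0.830, low) and Map1lc3a (0.864, high) in replicate 4.

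In WT cortex the same measure singled out Bmp6 (0.825, low) and Tmem98 (0.718, low) in replicate 1, Hsp90aa1 in replicate 2 (0.753, low), and Mx1 in replicate 3 (0.766, low). In TDP-43Q331K cortex it singled out Tmem260 in replicate 1 (0.735, high), Hmgcs1 in replicate 2 (0.653, low), Tac1 in replicate 3 (0.648, high), Egr2 (0.787, low) and Gja1 (0.830, high) in replicate 4, and Scd1 in replicate 5 (0.640, high). In TMEM106B-/- cortex it singled out Hnrnpa1 in replicate 2 (0.855, low), Tcn2 in replicate 3 (0.915, low), and Abca8a (0.770, low), Acat2 (0.746, low), Tac1 (0.794, low) and Tardbp (0.746, high) in replicate 5. In cortex of the combined genotype it singled out Angptl4 in replicate 1 (0.784, low), Reln in replicate 2 (0.917, high), Egr2 (0.717, low) and Hsp90aa1 (0.776, low) in replicate 3, and Npl in replicate 4 (0.845, low).

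For 14 named liver genes the effect of labelled TMEM106B loss differed between the TDP-43 backgrounds by the edgeR interaction test. The difference (log2, Q331K background minus WT background) was 2.91 for Gpat3, 2.47 for Tceal8, 2.20 for Wfdc2, 2.88 for Slc22a27, 1.94 for Renbp, 2.59 for Nt5e, 6.89 for Cyp2b13 and 1.23 for Cd36. It was -3.68 for Hsd3b5, -3.29 for Cyp4a12b, -1.68 for Mup20, -3.34 for Capn8, -4.05 for Ntrk2 and -2.74 for Clic5.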

How the results depend on the processing

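The alternatives that leave out libraries with extreme markers or add marker scores as covariates were chosen only after the result was seen, and the others before. Where a value moved and nothing below names a source, the cause was not tested. Of the counts of called genes under an alternative, 139 stayed within 1.5 times the reported count and 90 did not. Of the values for named genes, 4235 kept their direction and side of the threshold, 705 lost the call, 15 gained it and 3 reversed. For single lists 1593 were the same, 458 lost the call and 11 reversed. RLE size factors left all 12 counts within 1.5 times. The simulated changes recovered set the limit of detection, since liver recovered at most 22% of 1.5-fold changes.

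With limma-voom the called genes in liver were 324 (TMEM106B-/- against WT), 341 (TDP-43Q331K against WT), 1940 (combined genotype against WT), 1865 (combined against TDP-43Q331K), 376 (combined against TMEM106B-/-) and 320 (interaction). In cortex they were 1689, 11, 1818 and 781 for the first 4 of these. With DESeq2 they were 614, 391, 1847, 1309, 531 and 597 in liver, and in cortex 3 (TDP-43Q331K against WT), 1601 (combined against WT) and 819 (combined against TDP-43Q331K). With only the compared groups in the fit, where fewer samples set the spread, they were 60, 20 and 81 in liver (TMEM106B-/- against WT, TDP-43Q331K against WT, combined against TMEM106B-/-), and 2 and 104 in cortex (TDP-43Q331K against WT, combined against TDP-43Q331K). With the replicate block they were 13 (liver, TDP-43Q331K against WT), 1 (cortex, TDP-43Q331K against WT) and 120 (cortex, combined against TDP-43Q331K). With 1 surrogate variable they were 13 (liver, TDP-43Q331K against WT), 304 (liver, combined against TMEM106B-/-), 428 (cortex, combined against WT) and 175 (cortex, combined against TDP-43Q331K). With no filter on low counts the last of these was 171. Without the libraries with extreme markers they were 12 (liver, TDP-43Q331K against WT), and in cortex 2 (TDP-43Q331K against WT), 131 (combined against TDP-43Q331K) and 2 (interaction). With the marker scores as covariates cortex had 48, 9 and 17 (TMEM106B-/- against WT, combined against WT, combined against TDP-43Q331K).

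With each library left out in turn, liver counts ran from 55 to 353 (TMEM106B-/- against WT), 7 to 71 (TDP-43Q331K against WT), 681 to 1196 (combined against WT), 248 to 703 (combined against TDP-43Q331K), 77 to 155 (combined against TMEM106B-/-) and 51 to 189 (interaction). Cortex counts ran from 664 to 1394 (TMEM106B-/- against WT), 422 to 1535 (combined against WT), 53 to 1103 (combined against TDP-43Q331K) and 0 to 1 (interaction). The number of passing lists ran from 9 to 16 and 7 to 16 in liver (TMEM106B-/- and TDP-43Q331K against WT) and from 4 to 9 and 1 to 6 in cortex (TDP-43Q331K against WT, combined against TMEM106B-/-).

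The number of passing lists in liver was 14, 14, 16, 12, 17 and 12 in the order of the comparisons above, and 0, 0, 4, 3, 2 and 1 with an estimated correlation. In cortex it was 16, 7, 13, 14, 3 and 5, and 1, 1, 0, 0, 0 and 0 with an estimated correlation. With fry, which does not compare a list with other genes, liver had 4, 0, 10, 4 and 7 (without the combined genotype against TDP-43Q331K, which stayed within 1.5 times) and cortex 7, 1, 7, 2, 0 and 0. Without the libraries with extreme markers the numbers were 19 (liver interaction) and 6 (cortex, combined against TMEM106B-/-). With the marker scores as covariates cortex had 5, 4, 7 and 7 (TMEM106B-/-, TDP-43Q331K and the combined genotype against WT, combined against TMEM106B-/-).

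Tmem106b in liver was 0.1044 (limma-voom) and 0.002099 (1 surrogate variable) in TDP-43Q331K against WT, both against the reported sign, and ran from -0.1859 to 0.07131 with a library left out. In the combined genotype against WT it passed with only the compared groups (0.4895), limma-voom (0.5775), DESeq2 (0.4891) and 1 surrogate variable (0.5107), and ran from 0.3971 to 0.572 with a library left out. Against TDP-43Q331K the call was lost with only the compared groups (0.5599), with 1 surrogate variable (0.5086) and without the high acute phase livers (0.6007), and it ran from 0.4135 to 0.6706 with a library left out. In cortex, combined genotype against TDP-43Q331K, Tmem106b passed with limma-voom (0.1474) and DESeq2 (0.1361) and ran from 0.1076 to 0.174.

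Tardbp in liver reversed without the high acute phase livers, at 0.02432 (TMEM106B-/- against WT), 0.009753 (combined against WT), -0.01456 (combined against TMEM106B-/-) and -0.01003 (interaction), and with 1 surrogate variable at -0.01411 (combined against TDP-43Q331K). With a library left out it ran from -0.1705 to 0.004523, -0.1358 to 0.0392, -0.01424 to 0.073 and -0.00331 to 0.08455 in the pairwise comparisons just named. In cortex it passed with limma-voom in TDP-43Q331K against WT (0.1812). In the combined genotype against WT it reversed with limma-voom (-0.001865), 1 surrogate variable (-0.05701), the marker scores (-0.05923) and without the cortices with extreme markers (-0.01017), and ran from -0.01454 to 0.02668. Against TDP-43Q331K it passed with RLE size factors (-0.1766), limma-voom (-0.1831), DESeq2 (-0.1755), 1 surrogate variable (-0.2264), the marker scores (-0.2216) and without the cortices with extreme markers (-0.1999), and ran from -0.1892 to -0.1558.

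With the marker scores as covariates in cortex, TMEM106B-/- against WT, Serping1 (-0.08163), Cp (-0.004799) and Spp1 (-0.09016) reversed. So did the lists of astrocyte (adjusted p = 0.507, range over the alternatives 4.28e-05 to 0.515), brain vessel cell (0.92, range 3.03e-06 to 0.92), disease-associated microglia (0.955, from 0.00373), interferon response (0.955, from 0.00837), meninges and fibroblast (0.955, from 1.28e-17) and striatum (0.955, from 1.96e-06). The scores of meninges and striatum are themselves covariates, which takes those lists' differences out by construction. In the other comparisons those that reversed were meninges and fibroblast in TDP-43Q331K against WT (0.989, from 0.000306) and in the interaction (0.728, range 3.25e-06 to 0.967), brain vessel cell in the combined genotype against WT (0.995, from 0.000254), and striatum in the combined genotype against WT (0.891, from 5.62e-05) and against TDP-43Q331K (0.845, from 0.000217). Across genes, the correlation of the TMEM106B effects in cortex was 0.5703 with the marker scores, and that of the Q331K effects was -0.05933 over genes above a mean of 10 CPM.

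Other splits into groups of the same sizes were counted. In liver none called as many for TMEM106B-/- against WT (176 genes, highest other 68) or the interaction (115, 1, 1 of 60). Nor did any for the combined genotype against WT (1176, 5), TDP-43Q331K (658, 1) or TMEM106B-/- (173, 5). The pairwise 1 of 35 (the real split) is the lowest possible share and cannot exclude chance. For TDP-43Q331K against WT another split called more (44, highest other 114, 2 of 35). There 4 of 4 libraries correlated best with their own replicate number (0.0931 to 0.278), as in no other comparison. In cortex none called as many for TMEM106B-/- against WT (1097, highest other 35) or the combined genotype against WT (1038, 347) and TDP-43Q331K (298, 32), each 1 of 100. All did for TDP-43Q331K against WT (0, highest other 3, 100 of 100), the combined genotype against TMEM106B-/- (0, 309, 100 of 100) and the interaction (0, 2, 60 of 60). Splits with 114, 347 and 309 calls point to sample structure beyond genotype.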

Other observations

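In this part the settings that leave out libraries or add marker scores were chosen only after the result was seen. Further gene groups moved in liver by camera, each with a call that was lost with an estimated correlation. In the combined genotype against WT, glycolysis genes moved up with 4 of 18 called over all genes and adjusted over the list alone (adjusted p = 0.00787; adjusted p = 0.285 with an estimated correlation, 4 of 4 libraries), such as Eno1 (0.70 ± 0.13) and Gapdh (0.54 ± 0.11). NRF2 targets of the response to oxidants moved up with 3 risen and 1 fallen, or 5 and 1 adjusted over the list alone (adjusted p = 0.033; adjusted p = 0.466 with an estimated correlation), with Gsta1 (2.33 ± 0.49) and G6pdx (0.99 ± 0.26) higher. Targets of CAR and PXR moved up with 4 risen and 2 fallen, or 6 and 2 adjusted over the list alone (adjusted p = 0.0362; adjusted p = 0.581 with an estimated correlation), with Cyp2b10 at 3.38 ± 0.68, and did not pass without the high acute phase livers (median 0.07, adjusted p = 0.102). Genes of autophagy, bile acid synthesis and transport, glucose production and lipoprotein transport passed in no liver comparison.

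In cortex of libraries labelled TMEM106B-/-, synapse genes moved up against WT with 2 of 28 called, such as Stx1a (0.20 ± 0.03; list adjusted p = 0.0242; adjusted p = 0.52 with an estimated correlation). Inhibitory neuron genes moved up with 2 of 19 called, Calb1 (0.28 ± 0.07) and Reln (0.36 ± 0.10; list adjusted p = 0.0266; adjusted p = 0.363 with an estimated correlation), in 5 of 5 libraries. Homeostatic microglia genes moved up with 1 of 19 called, Tmem119 (0.36 ± 0.08; list adjusted p = 0.0145; adjusted p = 0.515 with an estimated correlation). Astrocyte genes moved up with 1 of 16 called, the glutamate transporter Slc1a3 (0.23 ± 0.05; list adjusted p = 0.0046; adjusted p = 0.515 with an estimated correlation). Red blood cell genes moved down with 1 of 6 called, Hba-a1 (-1.02 ± 0.29; list adjusted p = 0.041; adjusted p = 0.52 with an estimated correlation). Under the marker scores as covariates the astrocyte list turned direction (median -0.04, adjusted p = 0.507), inhibitory neuron (median 0.02, adjusted p = 0.489) and homeostatic microglia genes (adjusted p = 0.195) did not pass, and 0 genes were called in these lists and among red blood cell genes (median -1.04, adjusted p = 0.000624). The astrocyte list was also lost without the cortices with extreme markers (adjusted p = 0.104). Lysosome genes did not pass in cortex, with 2 risen and 2 fallen against WT (adjusted p = 0.161). In the combined genotype against WT, mitochondrially encoded genes moved up with 2 of 13 called, such as mt-Nd4l (1.15 ± 0.21; list adjusted p = 0.00352; adjusted p = 0.417 with an estimated correlation), in 4 of 5 libraries, and did not pass with the marker scores as covariates (adjusted p = 0.128).

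The acute phase gene Saa1 was at 2139 CPM in WT replicate 2, 2601 in TMEM106B-/- replicate 4 and 2318 in replicate 1 of the combined genotype in liver, and between 15.4 and 357.1 CPM in the other livers. Precursor and differentiating oligodendrocyte genes as a list did not pass in TMEM106B-/- against WT in cortex (adjusted p = 0.0661), and their median (0.02) and mean (-0.17) differed in sign.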
